A study of Rattus norvegicus with 10 samples.

How the data were processed

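The samples were RNA pools of the hypothalamic paraventricular nucleus of adult male Sprague Dawley rats, 10 to 12 weeks old. Per the labels, 5 pools came from rats dehydrated for 3 days and 5 from control rats, each pool held the nuclei of 5 animals, and each pool was hybridised to 1 Affymetrix Rat Genome 230 2.0 array, so that 10 arrays stood for 50 animals. The labels describe the pools as independently prepared from separate groups of animals, so the spread between arrays holds both biological and technical variation. The series title and every sample label name the paraventricular nucleus, whereas the design text of the series names the supraoptic nucleus at 1 point. The sample labels were followed. Groups came from the sample titles, and replicates were numbered in accession order, so that a number names a pool and pairs nothing across groups. The chip numbers in the titles ran in 1 block per group apart from control replicate 5, and no hybridisation date was used here, so an array batch and the group cannot be told apart.

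The deposited values were linear probe set signals, 1 per probe set and array, made by the authors with the Affymetrix software GCOS 1.2, per the submitters' processing notes. The signal algorithm, the background step and the detection calls were not given in the sources used here. The mean signal after trimming 2% at each end was 100 on all 10 arrays, so the authors had scaled each array to a common level. Array medians ran from 36.4 to 39.1. Such signals compress at the top of the scanner's range and hold background at the bottom, which makes large differences look smaller at both ends. The number of arrays limits the precision, and no count depth applies to arrays.

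The table held 31099 probe sets, of which 57 control probe sets were left out of the tests. Its 2 missing values both lay in control probe sets. Of the remaining 31042 probe sets, 20826 had 1 gene symbol in the platform annotation, 436 had several and 9780 were not listed there. Symbols were updated through Entrez identifiers for 20764 of the single-symbol probe sets. No gene was named from a probe set with several symbols, and identifiers are those of the array. The rat gene table used for the update gave names only, and no genome coordinates were used.

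Signals were used as deposited, without further scaling, as log2(signal + 3.72). The pseudocount was 0.1 of the median of the array medians, by a rule set for tables of this scale. Log2 differences and folds are on that scale, which understates the change of dim probe sets. Probe sets whose mean signal over all 10 arrays reached the 40th percentile were kept, which left 18629 with a mean of 24.1 or more. The groups were compared with lmFit and eBayes (trend on the mean level) of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Adjusted p below are from this fit unless another test is named. Errors of signals are SD over 5 pools, and errors of log2 differences are standard errors of the fit.

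There were 14 gene lists and 15 marker lists of other cell types and neighbouring regions. Each list was tested with camera of limma at a preset inter-gene correlation of 0.01, with the probe set of the highest mean signal standing for each gene, and adjusted over the 28 lists with 5 or more measured members. The red blood cell list had 2 measured members and was not tested as a list. Of 710 list entries, 601 matched a symbol on the array and 506 were tested. Members are counted as risen or fallen over all probe sets and, separately, adjusted over the list alone. RNA quality was compared through the log2 ratio of the 3 prime to the 5 prime control probe sets of Gapdh and beta-actin, with the sum and the median of the signals, by exact two-sided permutation over all 252 assignments of the arrays.

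The lists, the tests and the rule for named genes were set before the data were examined. The rule named the 12 genes with the largest rise and the 12 with the largest fall among changed probe sets with 1 symbol whose 5 dehydrated values all lay on one side of the 5 control values, 16 genes whatever their values, and up to 4 members of each list with the smallest p. Of the 16, Pcsk1 and Nos1 had no tested probe set with 1 symbol and were not analysed here. Alternatives were median centring, quantile normalization, other pseudocounts, no filter and a stricter filter (60th percentile), a fit without the variance trend, a robust fit, array weights, each array left out in turn, an inter-gene correlation estimated from the data, the rotation test fry, the mean over all probe sets of a gene, and the other probe sets of a named gene. Leaving out arrays for the quality measures was added after seeing the data.

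The fit was tested on simulated arrays made from the means and SDs of the 18629 probe sets of this comparison, with 200 probe sets changed in each of 5 simulated sets. At true log2 differences of 0.4, 0.8 and 1.6 it recovered 35.5%, 84.8% and 99.4% of the changed probe sets, and 5.9% of its calls were false. A list raised by 0.15 was called in 5 of 5 sets and 0 unchanged lists were called, in simulations whose genes varied independently of each other. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for the tables, the exact tests and the figures.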

Results

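Signals of 18629 probe sets were compared between the paraventricular nuclei of dehydrated and control rats, with 5 pools per group. The paraventricular nucleus holds the magnocellular neurons that make vasopressin and oxytocin and the parvocellular neurons that make releasing hormones, and water deprivation is a stimulus to its vasopressin neurons. The comparison asked which transcripts of this nucleus differ after 3 days of dehydration. Signal sums were 4102174 ± 36310 on the dehydrated and 4063319 ± 24393 on the control arrays (exact permutation p = 0.0794, n = 5 each, smallest possible p 0.0079). Pairwise correlations of the arrays ran from 0.959 to 0.978. Control replicate 5 stood apart on the first principal component, which held 20.7% of the variance, at 37.2 against -14.4 to 3.69 for the other arrays, and it had the lowest array weight, 0.385. Dehydrated replicate 2 had a mean correlation of 0.9705 with its own group and 0.9729 with the controls. On the first component it lay with the dehydrated arrays, at -5.73. On the second it lay at 5.87, where the other dehydrated arrays lay from -19.9 to -5.88, control replicate 5 at -12.7 and the other controls from 9.46 to 17.9.

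Dehydration was accompanied by a large rise of a small set of transcripts. Tnfaip6, which encodes a secreted hyaluronan-binding protein, rose from 22.1 ± 3.78 in control to 132 ± 14.4 in dehydrated pools (SD, n = 5 each), a log2 difference of 2.40 ± 0.13 (adjusted p = 2.3e-08). Caprin2, an RNA-binding protein, rose from 211 ± 29.8 to 766 ± 119 (log2 1.84 ± 0.11, adjusted p = 6.6e-08), and the opsin gene Opn3 from 87.1 ± 12.8 to 290.0 ± 38.2 (log2 1.69 ± 0.11, adjusted p = 1.5e-07). The zinc finger gene Giot1 rose from 20.9 ± 2.92 to 76.3 ± 18.3, a log2 difference of 1.68 ± 0.16. Falls were smaller, and the insulin-like growth factor binding protein gene Igfbp5 fell by 0.64 ± 0.07 on the log2 scale, from 222 ± 7.25 to 141 ± 10.3 (adjusted p = 3.4e-04).

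In all, 108 probe sets changed, of which 74 were higher and 34 lower in dehydrated pools. A change of 2-fold or more was found for 11, all of them higher, and for 7 at 4 times the pseudocount, 3 at a pseudocount of 64 and 7 with the stricter filter. Among the 108, 86 had 1 symbol and stood for 85 genes, and in 105 all 5 dehydrated values lay on one side of the 5 control values. Over all tested probe sets, 3.36% had groups that did not overlap, against 0.794% by chance. An unadjusted p under 0.05 was found for 2368 of the 18629. The other genes among the 12 largest rises were Oacyl (log2 1.29), the sulfotransferase Sult1a1 (1.18), Camk2g (1.17), Atp6ap1l, Kcnn3, a small-conductance calcium-activated potassium channel (0.99), Prpf4b (0.92), Fezf2 (0.92) and Arhgdib (0.91), with adjusted p from 6.2e-05 to 0.018. Another probe set of Camk2g differed by -0.19 (adjusted p = 0.483), and 3 other probe sets of Prpf4b by 0.02, -0.07 and -0.19 (adjusted p from 0.713 to 0.936), so the rise of both genes was that of a single probe set. The 12 largest falls ran from Echdc2, which fell by 0.92 ± 0.19, and the imprinted gene Plagl1, which fell by 0.80 ± 0.15, to Mmp15 and Rnf180, which each fell by 0.41 ± 0.08. Between them lay Hhatl, Igfbp5, the oligodendrocyte gene Ermn, Pmel, the neuronal pentraxin gene Nptx1, Armc8, apolipoprotein D (Apod) and Sema4d. A second probe set differed by -0.01 for Igfbp5, by -0.30 for Ermn and by 0.01 for Armc8, with no call in any of them. Of these 12 falls, Hhatl, Igfbp5 and Apod passed with each array left out in turn. The number of arrays whose removal ended the call was 8 for Echdc2, 7 for Plagl1, 3 for Ermn, 8 for Pmel, 8 for Nptx1, 9 for Armc8, 10 for Sema4d, 7 for Mmp15 and 6 for Rnf180. Among the 12 rises it was 1 for Prpf4b and 1 for Fezf2, dehydrated replicate 3 in both (adjusted p = 0.0549 and 0.0520 without it), and 0 for the others. Other settings ended the calls of Nptx1 (4 settings), Armc8 and Sema4d (3 each), Echdc2, Plagl1, Ermn, Rnf180 and Prpf4b (2 each) and Pmel (1), Prpf4b without a filter (adjusted p = 0.0554) and without the variance trend (0.0833). With each array left out in turn, 40 of the 108 probe sets were changed every time, 34 of them higher and 6 lower. The 6 lower were those of Igfbp5, Hhatl and Apod and probe sets annotated with globin genes. The count of changed probe sets ran from 46 without dehydrated replicate 3 to 148 without control replicate 5.

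**Figure D1:**
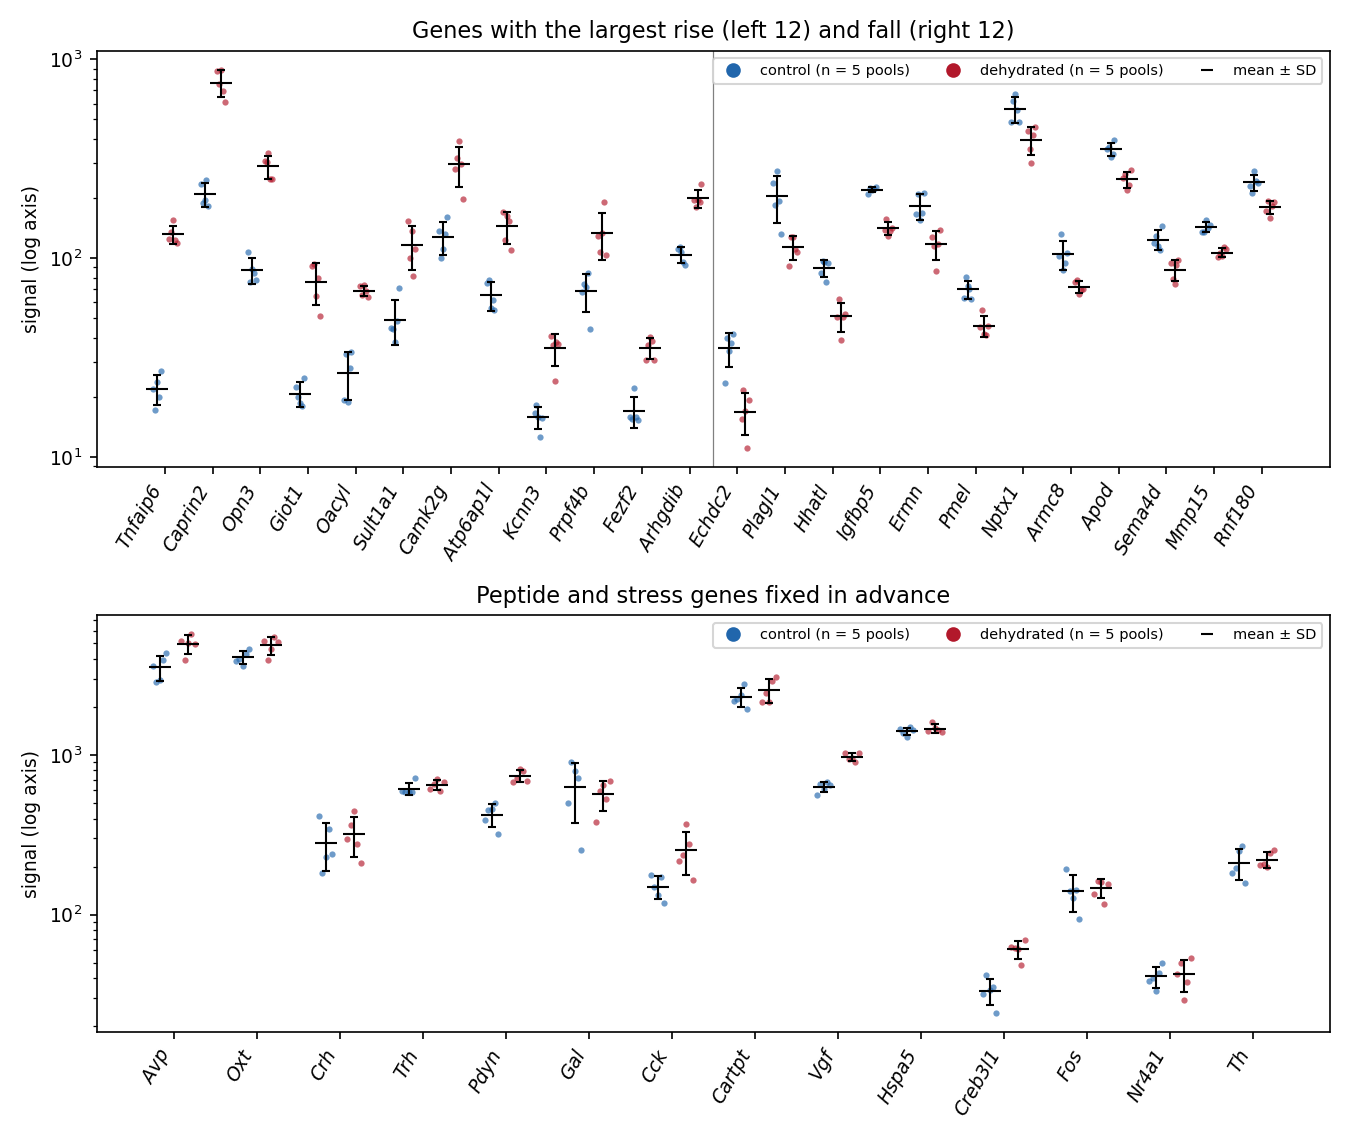
Signal of each array (points, log axis) with the mean and SD of the 5 pools per group, for the 12 largest rises and 12 largest falls (top) and for the genes fixed in advance (bottom). The dehydrated pools of Tnfaip6 average 132 against 22.1 in control, while those of Fos and Nr4a1 overlap the control pools.

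Among the peptide genes of magnocellular neurons, prodynorphin and Vgf rose. Pdyn went from 423 ± 69.3 in control to 740 ± 62.4 in dehydrated pools (log2 0.81 ± 0.10, adjusted p = 5.7e-04), and Vgf, which encodes a secreted neuropeptide precursor, from 631 ± 44.4 to 972 ± 54.5 (log2 0.62 ± 0.06, adjusted p = 6.2e-05). Vasopressin itself had signals of 3531 ± 633 and 4956 ± 643, a log2 difference of 0.50 ± 0.11 that missed the threshold by little (adjusted p = 0.0504). It passed without dehydrated replicate 2 (adjusted p = 0.0172) and without control replicate 5 (0.0132), and also with array weights (0.0128), with larger pseudocounts (0.0467 and 0.0443) and with the stricter filter (0.0473). Its signals lay near the top of the array's range, where the highest signal was 4558 to 6284 per array. Cholecystokinin differed by 0.70 ± 0.16 (adjusted p = 0.0665, and 0.0184 without dehydrated replicate 5) and oxytocin by 0.24 ± 0.08 (adjusted p = 0.218). Galanin, Cartpt and Th gave adjusted p of 0.943, 0.599 and 0.812. Of the 19 measured members of the magnocellular list 2 rose, 0 fell and 17 did not pass, and 5 rose and 1 fell when adjusted over the list alone. The list was shifted upwards by camera (adjusted p = 0.00223), with an adjusted p of 0.128 with an estimated correlation. Markers of oligodendrocytes were shifted downwards in the same pools (median log2 -0.28), and those of the anterior, lateral and posterior hypothalamus too (median -0.32), with adjusted p of 0.138 and 0.520 with an estimated correlation.

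Single parvocellular genes did not pass. Crh, the corticotropin-releasing hormone gene, had 282 ± 94.3 in control and 320 ± 89.7 in dehydrated pools (log2 0.19 ± 0.20, adjusted p = 0.726). Trh differed by 0.08 ± 0.07 (adjusted p = 0.648). Of the 13 measured parvocellular and autonomic genes none passed in limma (0), and 2 were higher when adjusted over the list alone. An unadjusted p under 0.05 was found for 3, against 2368 of 18629 over all probe sets. The smallest p were those of the angiotensin receptor Agtr1a (log2 0.56) and somatostatin (log2 0.50). With array weights both genes passed (adjusted p = 0.0291 and 0.0462), and Agtr1a also passed without control replicate 5 (0.0297). By camera the list was shifted upwards (adjusted p = 0.00371, and adjusted p = 0.138 with an estimated correlation), and 11 of its members were positive.

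Genes of the secretory pathway were shifted upwards as lists by small amounts, through few single genes. The median log2 difference was 0.035 for granule genes and 0.059 for folding genes. With an estimated correlation neither list passed, at an adjusted p of 0.138 for granule genes and 0.128 for folding genes. Of 28 granule and prohormone processing genes, Vgf and the peptide-amidating enzyme Pam rose, Pam by 0.28 ± 0.06 (adjusted p = 0.0313, a call ended by the removal of any of 6 arrays, up to 0.0968 without dehydrated replicate 3, and by 3 other settings), 26 did not pass, and 24 were positive. The list had a camera adjusted p of 0.0022 (0.138 with an estimated correlation). Of 36 genes of protein folding and the unfolded protein response, the transcription factor genes Creb3l1 and Atf4 rose and 6 rose when adjusted over the list alone. Creb3l1 went from 33.5 ± 6.33 to 60.6 ± 7.61 (log2 0.80 ± 0.14, adjusted p = 0.0159, and 0.0535 without dehydrated replicate 3) and Atf4 from 627 ± 52.1 to 795 ± 23.4 (log2 0.35 ± 0.06, adjusted p = 0.0146, a call ended by the removal of any of 3 arrays, up to 0.0538 without dehydrated replicate 4). The chaperone gene Hspa5 differed by 0.06 ± 0.06 (adjusted p = 0.713), and Fkbp11 and Asns by 0.47 and 0.32 without passing. That list had a camera adjusted p of 0.00248 (0.128 with an estimated correlation).

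Activity-dependent genes were shifted upwards, while Fos and Nr4a1, which neurons transcribe within minutes of stimulation, did not pass. The list's camera adjusted p was 2.8e-04, with an adjusted p of 0.128 with an estimated correlation. Of 27 measured members, Giot1 and Vgf rose, 25 did not pass and 22 were positive, with 5 higher and 1 lower when adjusted over the list alone. Fos had 140 ± 36.2 in control and 146 ± 19.9 in dehydrated pools (adjusted p = 0.840), and Nr4a1 41.1 ± 6.18 and 42.6 ± 9.72 (adjusted p = 0.956). Rgs4 and Bdnf differed by 0.40 and 0.42 without passing. Of 19 glucocorticoid responsive genes, Sult1a1 and the metallothionein gene Mt2A rose, Mt2A by 0.39 ± 0.08 (adjusted p = 0.0441, a call ended by the removal of any of 9 arrays, up to 0.130 without dehydrated replicate 3), 17 did not pass, and 5 rose and 1 fell when adjusted over the list alone. Fkbp5 and Cdkn1a differed by 0.35 and 0.48 without passing. Its camera adjusted p was 0.0266, and the adjusted p was 0.360 with an estimated correlation. The 18 osmotic and tonicity response genes did not shift as a list (camera adjusted p = 0.802), with 10 positive and 8 negative. In limma 0 were past the threshold. An unadjusted p under 0.05 was found for 7, a larger share than the 2368 of 18629 over all probe sets. Sgk1 was at 0.45, Akr1b1 at 0.21 and the water channel Aqp4 at -0.16, where 2 other probe sets of Aqp4 had 0.18 and -0.22.

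By camera at the preset correlation alone, ribosomal protein and oxidative phosphorylation genes were shifted upwards by small amounts, and cholesterol synthesis genes downwards. Of 38 ribosomal protein genes 27 were positive (median log2 0.04, camera adjusted p = 0.0274, and adjusted p = 0.684 with an estimated correlation), of 66 oxidative phosphorylation genes 42 (median 0.03, adjusted p = 0.0493, and 0.611 with an estimated correlation), and of 21 cholesterol synthesis genes 14 were negative (median -0.05, adjusted p = 0.0224, and 0.589 with an estimated correlation). No member of these 3 lists passed in limma or over the list alone (0 each, with 5, 6 and 6 at an unadjusted p under 0.05). Over all probe sets that p was found for 2368 of 18629, a share that the ribosomal genes were close to and the oxidative phosphorylation genes lay under. Under quantile normalization the ribosomal list turned to the other direction (adjusted p = 0.811) and the oxidative phosphorylation list lost its call (adjusted p = 0.679). Median centring ended both calls too (camera adjusted p = 0.0849 and 0.186). Among the channels Kcnn3 rose, the sodium channel gene Scn3a differed by 0.44 ± 0.10 (adjusted p = 0.0506), and the other 28 members, Scn3a included, did not pass. Scn3a passed with larger pseudocounts (adjusted p = 0.0475 and 0.0419), the stricter filter (0.0456) and array weights (0.0274). It also passed without dehydrated replicate 2 (0.0484) and without control replicate 5 (0.0250). Adjusted over the list alone, 3 channel genes rose and 1 fell. That list's median was -0.03 and its mean 0.01, and camera and fry gave opposite directions, neither past the threshold (camera adjusted p = 0.725). The lists of GABA and glycine receptors (adjusted p = 0.802, with Gabra2 at 0.52), glutamate receptors (0.670) and axon growth genes (0.809) did not shift. The median and the mean differed in sign for GABA and glycine receptors (-0.04 and 0.02) and axon growth genes (0.00 and -0.01), and among markers for pericytes (0.01 and -0.05) and ependyma (-0.02 and 0.01), and camera's direction was down in all 4.

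**Figure D2:**
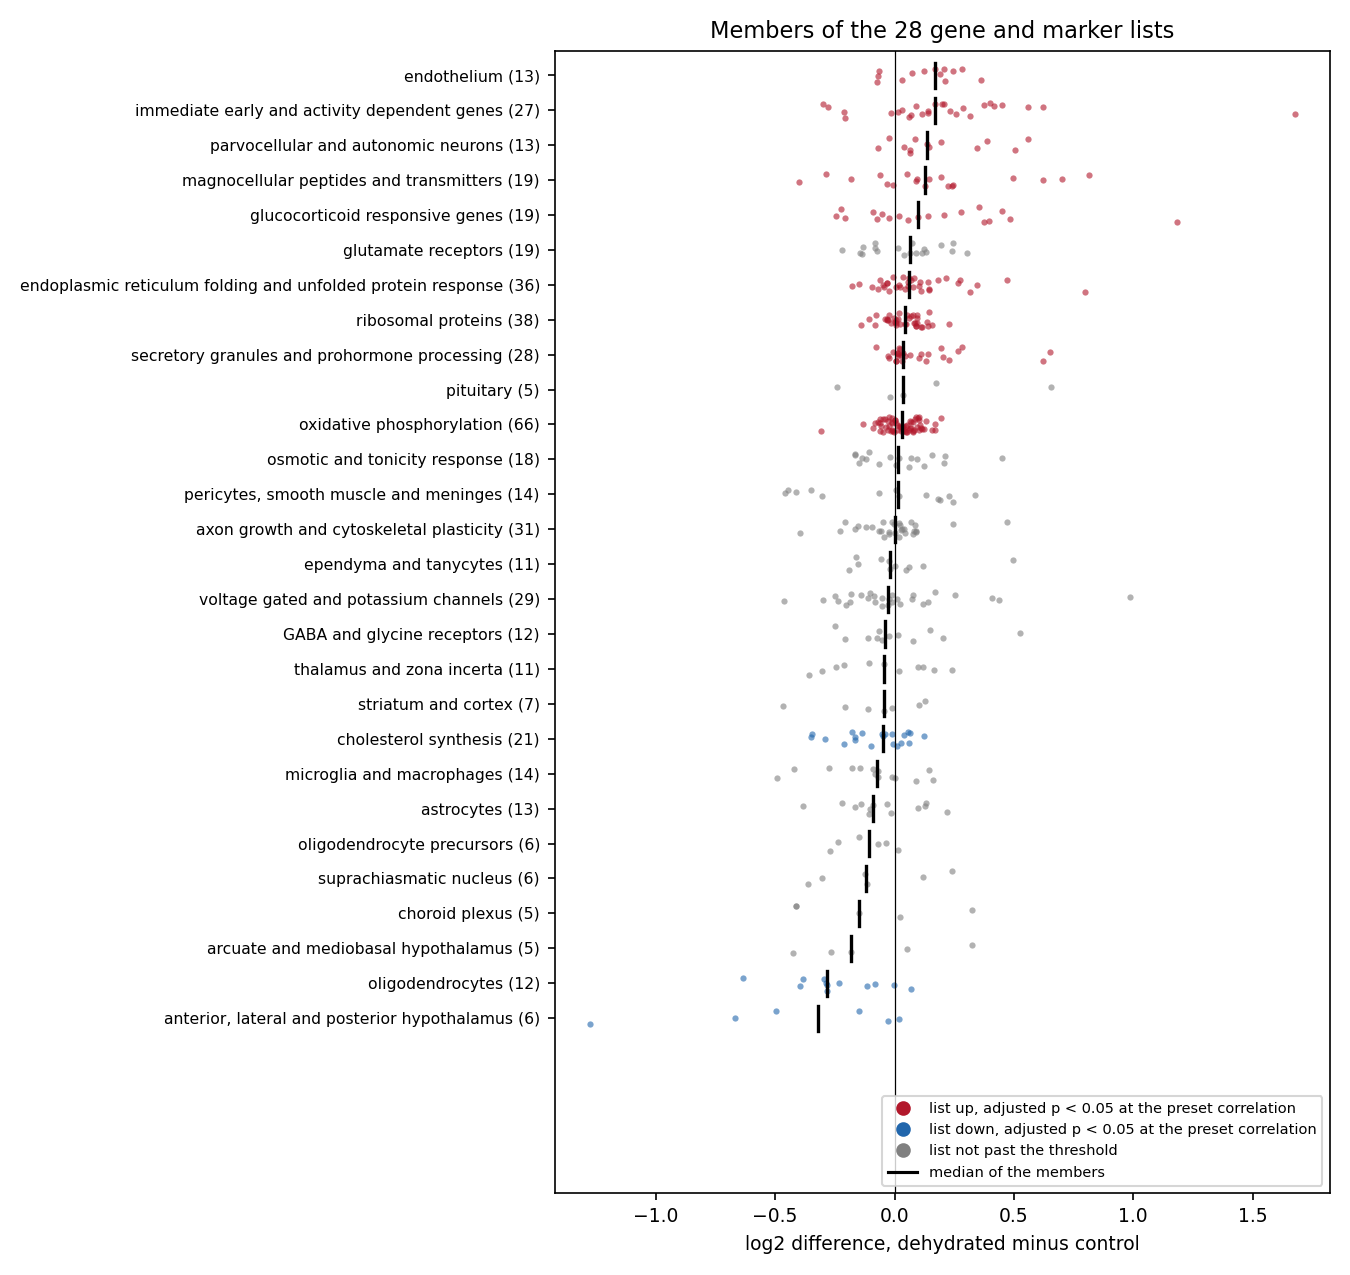
Log2 difference of each measured member of the 28 lists (points, with the number of members in brackets) and the median of each list (black line), coloured by the camera test at the preset correlation. The 12 coloured lists are past the threshold there, and 0 of them with an estimated correlation. The oligodendrocyte median lies at -0.28 and that of the immediate early genes at 0.17.

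Markers of other cells and regions also differed between the groups. Of 12 oligodendrocyte genes 11 were negative. Ermn fell by 0.63 ± 0.12, from 184 ± 26.8 to 117 ± 19.6 (adjusted p = 0.0255, a call ended by the removal of any of 3 arrays, up to 0.0792 without control replicate 2), and 8 fell when adjusted over the list alone. Cldn11, Cnp and Mobp differed by -0.28, -0.28 and -0.23 without passing over all probe sets, and 2 other probe sets of Mobp by 0.02 and -0.15. The list's camera adjusted p was 2.0e-06, with an adjusted p of 0.138 with an estimated correlation. The region list of the anterior, lateral and posterior hypothalamus was shifted downwards (camera adjusted p = 0.0224, and adjusted p = 0.520 with an estimated correlation), with 3 of 6 members lower over the list alone. Hypocretin, made by lateral hypothalamic neurons, had 1586 ± 875 in control and 661 ± 377 in dehydrated pools (log2 -1.28 ± 0.44, adjusted p = 0.233), and Hdc and Nkx2-1 differed by -0.67 and -0.50. Endothelial genes were shifted upwards (10 of 13 positive, adjusted p = 0.0224, and 0.520 with an estimated correlation), the smallest p being that of Slco1a4 (log2 0.28). Of 7 probe sets annotated with globin genes alone, 6 fell, by 0.54 to 0.97, including that of Hbb, from 659 ± 80.0 to 419 ± 94.1 (adjusted p = 0.0305, a call ended by the removal of any of 6 arrays, up to 0.0842 without control replicate 2), while the red cell gene Alas2 differed by -0.38 ± 0.22 (adjusted p = 0.477). In the fit without the variance trend Atf4, Pam, Mt2A, Ermn and Hbb did not pass (adjusted p from 0.0942 for Ermn to 0.155 for Pam).

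The other marker lists did not pass. Their adjusted p were 0.181 for astrocytes, 0.0892 for oligodendrocyte precursors, 0.0790 for microglia and macrophages, 0.604 for pericytes, smooth muscle and meninges, 0.952 for ependyma and tanycytes and 0.447 for choroid plexus. For neighbouring tissue they were 0.508 for the suprachiasmatic nucleus, 0.381 for the arcuate nucleus, 0.670 for thalamus and zona incerta, 0.377 for striatum and cortex and 0.802 for pituitary. The astrocyte gene Gfap had a log2 difference of -0.38 ± 0.09 (adjusted p = 0.0553) and the microglial gene Aif1 -0.42 ± 0.11 (adjusted p = 0.0880). Gfap passed with quantile normalization (0.0399), a pseudocount of 64 (0.0497), the stricter filter (0.0496) and array weights (0.0289). It also passed without dehydrated replicate 2 (0.0192) or 5 (0.0425). Aif1 passed with array weights (0.0224), without dehydrated replicate 2 (0.0486) and without control replicate 5 (0.0250). The log2 ratio of the 3 prime to the 5 prime Gapdh control was 1.58 ± 0.22 in dehydrated and 1.41 ± 0.21 in control arrays (exact permutation p = 0.254, n = 5 each), and that of beta-actin 2.84 ± 0.17 and 2.70 ± 0.33 (exact permutation p = 0.516). Every array had more signal at the 3 prime end, with ratios from 2.07 to 3.58 for Gapdh and from 4.48 to 8.38 for beta-actin. Control replicate 5 was lowest for both. Median signals were 37.6 ± 0.993 and 37.1 ± 0.770 (exact permutation p = 0.389). All 4 quality comparisons had adjusted p from 0.317 to 0.516 by the exact permutation test.

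**Figure D3:**
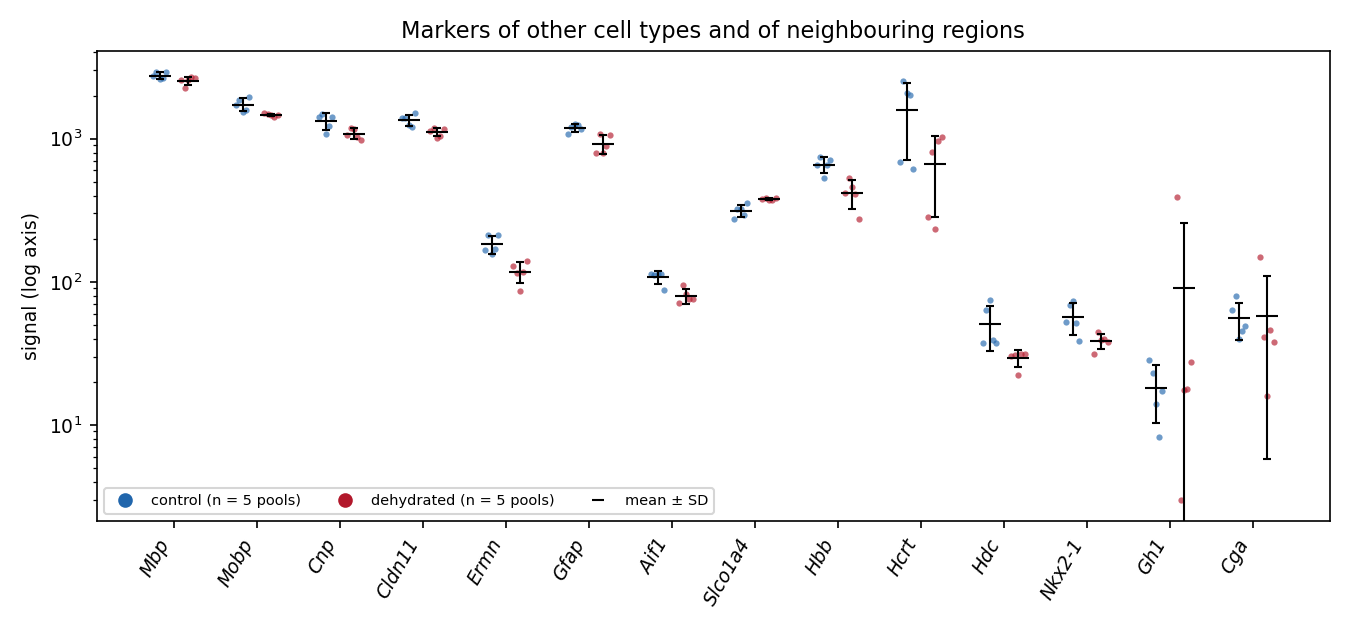
Signal of each array (points, log axis) with the mean and SD of the 5 pools per group, for markers of other cell types and of neighbouring regions. Ermn averages 117 in dehydrated and 184 in control pools. The lower SD bar of Gh1 in dehydrated pools runs off the log axis because 1 pool stands at 389.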

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

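Apart from the test of an array-wide rise of dim probe sets and the count of splits for the oligodendrocyte list, the tests in this part were chosen after the results they measure had been seen. An array was set apart where its gap to the nearest array of its group exceeded 0.71 of the group's range, which chance gives in about 1 group in 20. It happened in 14 of 290 groups tested, where chance gives about 14.5, so such arrays were no more frequent than chance gives. Control replicate 5, whose chip number lay apart from those of the other controls, held 5 of them, with a signal of 715.7 for Trh (the other controls 586.6 to 592.1), 25.9 for Mc4r (38.3 to 44.2), 176.6 for Scn3a (245.0 to 261.6), 87.6 for Aif1 (112.4 to 113.5) and a log2 ratio of the 3 prime to the 5 prime Gapdh control of 1.048 (1.422 to 1.54). Dehydrated replicate 3 held 3, with 24.1 for Kcnn3 (the other dehydrated pools 36.7 to 40.7), 26.8 for Lhx1 (36.9 to 41.2) and 22.2 for Hdc (30.5 to 31.5). Dehydrated replicate 5 had 1239 for Pam (1337 to 1374) and 64.5 for Ttr (156.3 to 197.1), dehydrated replicate 4 had 835.7 for Atf4 (774.8 to 791.5), dehydrated replicate 1 had 691.9 for Scn2b (781.0 to 812.0) and 210.2 for Prl (0.7 to 7.6), and control replicate 3 had 22.4 for Fezf2 (15.4 to 15.9).

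The rise of 74 probe sets was set against a larger share of paraventricular tissue in the dehydrated pools. Trh, Crh, Sim1 and Oxt, made in the nucleus, differed by 0.22 ± 0.10 on average, with an upper bound of 0.42 at 2 standard errors (0.50 without Oxt, whose signals lay near the top of the range). The highest difference among the 31 measured magnocellular and parvocellular genes was 0.81 ± 0.10, for Pdyn. Tnfaip6, Caprin2, Opn3 and Giot1 rose by 1.68 to 2.40, which argues against tissue share as the whole cause of their rise. The smallest of the 12 largest rises was 0.91 ± 0.09, within error of Pdyn, and the 12 were picked as the largest. For the rest of the 12 and for the other 62, whose median rise was 0.55, tissue share stays open. Pdyn, Cck, Vgf and Agtr1a lay above that median, and genes of the nucleus may themselves respond to dehydration. The lower markers of the anterior, lateral and posterior hypothalamus go in the direction a larger share would give. Their camera adjusted p was 0.520 with an estimated correlation, and 22 of 100 splits gave a camera p as small. Control replicate 5 did not produce the rise, since 92 probe sets were higher without it. Of 100 splits of the arrays, out of 126 possible, 1, the real one, gave as many changed (108, highest other 25), higher (74, highest other 4), lower (34, highest other 21) and 2-fold changed probe sets (11, highest other 2). These counts argue against no difference at all between the groups. They do not vouch for single calls, since every other split mixes the 2 groups. The 25, of which 21 were lower, came from the split that exchanged dehydrated replicate 2 and control replicate 5. On the second component these 2 arrays lay on the side of the other group, at 5.87 and -12.7. The remaining mixed splits gave at most 2 changed probe sets. With each array left out in turn, 34 higher and 6 lower probe sets were changed every time. The 6 lower were those of Igfbp5, Hhatl and Apod and globin probe sets with log2 differences of -0.97, -0.58 and -0.54. These lower calls are thus partly red blood cell transcripts. An array batch that runs with the group cannot be told apart from dehydration, which remains the open biological explanation.

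The lower oligodendrocyte markers were weighed against fewer oligodendrocytes in the dehydrated pools and against a single array. The members' differences, weighted by their precision, spread more than in most assignments of the arrays (exact permutation p = 0.0159, and 0.00794, the smallest possible, for the 8 members with a mean signal under 1000, a test added after the first was seen). This test cannot decide whether the falls were unequal. In mixed assignments a common fall widens the variance within groups, which lowers the weighted spread there. Of the 12 members 11 were negative, from -0.63 for Ermn to -0.002 for Mal, and Fa2h differed by 0.07. The members' SD was 0.19, and that between probe sets of the same gene was 0.18, as for Mbp at -0.12, -0.28 and -0.60. That 0.18 rests on 5 genes whose further probe sets were dimmer than those used for the list. The spread of the members' differences therefore does not decide for or against fewer cells. No single array carried the call at the preset correlation, since the highest camera adjusted p there with any array left out was 2.7e-04. Of the 100 splits 4, the real one included, gave a camera p as small as the real 7.3e-08, the smallest other being 1.2e-09, which is fewer than 5 of 100 for this list by itself but makes no allowance for its having the smallest p of the 28 lists, and with an estimated correlation the adjusted p was 0.138, so chance is not firmly excluded. A smaller share of oligodendrocytes or white matter in the dissected tissue and a response of oligodendrocytes to dehydration all remain open.

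Dehydrated replicate 1 held transcripts of pituitary hormones. Gh1 stood at 389 there against 3.0 to 28.4 in the other 9 arrays, Prl at 210 against 0.7 to 7.6, and Cga at 149 against 15.8 to 79.7, and 6 of the 7 hormone genes of the fixed list were highest in that array, Lhb being the exception. For Gh1 and Prl an array-wide rise of dim probe sets is argued against. Of 16965 probe sets as dim, 2 (0.012%) were 5-fold or more above the next array, where 2 of the 7 hormone genes were. Pomc, Cga, Tshb and Fshb exceeded the next array by 3.23-fold, 1.87-fold, 1.75-fold and 1.30-fold. For them the test cannot decide, since it counts gaps of 5-fold or more. That array also had the highest median signal, 39.1, and the lowest share of signals under 10, 19.9%. Pituitary RNA in that pool is a candidate explanation, found from the same values, and no biological explanation was tested because the labels set this pool apart in nothing. Without dehydrated replicate 1, 70 probe sets changed, 56 of them higher and 14 lower.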

How the results depend on the processing

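All settings except the left-out arrays for the quality measures were planned. Against 108 changed probe sets, the count was 64 without a filter (58 of them shared), 45 without the variance trend (40 shared) and 201 with array weights (108 shared); 46, 38 and 127 were higher with median centring, without the trend and with array weights, and 14, 7 and 74 were lower without a filter, without the trend and with weights. Changes of 2-fold or more numbered 7 at 4 times the pseudocount, 3 at a pseudocount of 64 and 7 with the 60th percentile filter. With an array left out the counts ran from 46 to 148 changed, 38 to 92 higher and 8 to 56 lower. Fewer arrays were tested there, and changed probe sets numbered 70, 46 and 50 without dehydrated replicates 1, 3 and 4 and 56, 57, 66 and 71 without control replicates 1 to 4. Lower ones numbered 53 without dehydrated replicate 2 and 56 without control replicate 5.

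All 12 list calls ended with an estimated correlation, which allows for members that vary together: 0.128 for magnocellular, folding and immediate early genes, 0.138 for parvocellular, granule and oligodendrocyte genes, 0.360 for glucocorticoid genes, 0.520 for endothelium and for anterior, lateral and posterior hypothalamus, 0.589 for cholesterol, 0.611 for oxidative phosphorylation and 0.684 for ribosomal genes. With fry the adjusted p were 0.0502 (parvocellular), 0.0971 (glucocorticoid), 0.290 (endothelium, oxidative phosphorylation and the anterior, lateral and posterior hypothalamus), 0.309 (cholesterol) and 0.432 (ribosomal). The mean over probe sets gave 0.1502 for cholesterol, 0.0888 for endothelium and 0.0868 for oxidative phosphorylation. For oxidative phosphorylation, median centring gave 0.186, quantile normalization 0.679, the larger pseudocounts 0.0507 and 0.0527 and no filter 0.0992. For ribosomal genes, median centring gave 0.0849, no filter 0.0906 and quantile normalization turned the direction (0.811). No filter gave 0.114 for the anterior, lateral and posterior hypothalamus and array weights 0.0594 for cholesterol. Calls appeared for astrocytes (0.0211, quantile) and microglia (0.0275 without a filter and 0.0398 with the 60th percentile filter). The cause was not tested for any of these. With arrays left out, adjusted p ran from 0.0025 to 0.0813 (anterior, lateral and posterior hypothalamus), 0.00409 to 0.163 (cholesterol), 0.00153 to 0.157 (endothelium), 0.0032 to 0.0659 (glucocorticoid), 0.00587 to 0.243 (oxidative phosphorylation), 8.9e-04 to 0.247 (ribosomal), 0.0274 to 0.647 (astrocytes), 0.0458 to 0.196 (microglia) and 0.0359 to 0.450 (oligodendrocyte precursors).

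Of 31 named genes past the threshold, 15 stayed past it, on the probe set used, in every setting and with every array left out. Among them were Tnfaip6, Caprin2, Opn3, Pdyn and Vgf, and also Camk2g and Igfbp5, whose other probe sets (-0.19 and -0.01) did not pass. Of the 31, none reversed its direction except by another probe set (Camk2g -0.19, Prpf4b -0.0707 and -0.19, Armc8 0.0118). The named genes' calls ended in 30 cases of other settings and 93 of left-out arrays and appeared in 18 and 12. The difference in the signal sum ran from 25440 to 48590 with an array left out and passed without dehydrated replicate 2 alone (exact permutation p = 0.0318, before adjustment), while the other quality measures stayed above the threshold with every array left out. Signals near background or near the top of the range limit what the arrays resolve.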

Other observations

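The Atf4 target list and its tests were written down before those genes' values were looked at, the weight given to the splits in reading them was raised afterwards, and the genes named next were chosen after their values were seen. Outside the naming rule, Rasd1, a Ras-like gene first found as induced by dexamethasone, rose from 136 ± 5.60 in control to 246 ± 21.9 in dehydrated pools (log2 0.83 ± 0.08, adjusted p = 3.9e-05). Both probe sets of Ap1s2, a subunit of a clathrin adaptor, rose, by 0.38 and 0.32, and the sorting receptor Sorcs1 rose by 0.56 (adjusted p = 0.0313). Sema3e, a secreted guidance cue, rose by 0.63, the complement inhibitor Cd55 by 0.86, the efflux transporter Abcg2 by 0.82 and 1 probe set of the endothelial adhesion gene Icam2 by 0.77, its other being at 0.52 (adjusted p = 0.135). For Ppargc1a, a coactivator of mitochondrial genes, 1 dim probe set rose by 0.84 while 2 others differed by -0.09 and -0.03, so no change of the gene as a whole can be read from it. Glud1, Fads1 and Isyna1 fell by 0.32, 0.31 and 0.40, a second probe set of Glud1 being at -0.35 without passing.

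Atf4, Cars1 (log2 0.41) and the cationic amino acid transporter Slc7a1 (log2 0.43) rose together, each of the last 2 by 1 probe set with the others positive but not past the threshold, and the hypothesis was tested that other targets of the stress regulator Atf4 rise too. Of 28 targets written down, 25 were measured and 19 were positive (median log2 0.13), with 0 past the threshold in limma over all probe sets. An unadjusted p under 0.05 was found for 10 of the 25, against 2368 of 18629 over all probe sets. Camera gave p = 0.00272 at the preset correlation, but p = 0.0791 with an estimated correlation, and fry gave p = 0.0143. Of 100 splits of the arrays 5, the real one included, gave a camera p as small, the smallest other being 5.0e-04, so chance cannot be excluded. Slc7a11 and Phgdh, both on that list, differed by -0.48 and -0.32, Eif4ebp1 by 0.46 and Mthfd2 by 0.75. The data leave this hypothesis open.

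Of the 100 splits 3, the real one included, gave as many lists past the threshold as the real 12, the highest other split giving 14, which is fewer than 5 of 100, but 0 lists were past the threshold with an estimated correlation, so chance is not firmly excluded for the number of lists. Taken list by list, a camera p as small as the real one came from 2 of the 100 splits for folding genes, 3 each for magnocellular and immediate early genes, 5 for granule genes and 9 for parvocellular genes. It came from 14 for glucocorticoid genes, 21 for endothelium, 22 for the anterior, lateral and posterior hypothalamus, 23 for cholesterol synthesis, 25 for oxidative phosphorylation and 40 for ribosomal proteins.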
